A study of Mus musculus with 2 samples.

How the data were processed

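CUT&Tag libraries were made from retinal nuclei with a Rac1 antibody and amplified with 15 PCR cycles, per the labels. Adapters were trimmed with cutadapt 1.9.1 and reads were aligned with Bowtie2, to the build mm9, as far as the names in the submitters' processing notes go; their role and order are not given there. The peak caller, its settings, any background library and the treatment of duplicate reads are not given in the sources used here. Each library has its own list of peaks, so peaks were taken as called per library. The signal, a pileup per peak, was deposited by the authors with no stated scaling. The fold enrichment, a ratio over background, and the -log10 p and -log10 q values are also those deposited by the authors; 2 of their column headings held a spreadsheet error, and these columns were read as -log10 p and -log10 q from their place and values. The positions, lengths, distances to the TSS and gene coordinates (other values per peak) are the authors', per the file headers, as are the annotation class and the gene of each peak. These scores were used to describe, rank or filter peaks within a list. Some are also given side by side for the 2 libraries without a test, and a background computed from them was compared as a ratio.

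The lists hold only peaks past the caller's threshold, so a gene without a peak is not shown to be unbound. The lowest -log10 q was 2.00 in control and 1.82 in COH, and the lowest -log10 p was 5.05 and 5.07. The number of reads is unknown. An implied background per peak was computed as (pileup + 1) / fold - 1, a form assumed from a widely used caller; 115 control peaks and 52 COH peaks, with 15 and 9 different pileups, shared the lowest value within 0.001, 1.18 in control and 1.14 in COH. The form was not stated by the authors.

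The 2 libraries were grouped by their labels into control and COH at 1 week, with 1 library per group. Hence no test between the conditions was made and no p-value is given. Peaks of the lists were compared by an overlap of at least 1 bp, and the COH peaks were placed at random 1000 times within the covered span of their chromosomes. Shares have exact Clopper-Pearson 95% intervals. PCR reads without molecular identifiers are not independent molecules, so the intervals cover counting error only. Clustered peaks were those in windows of 100 kb with at least 5 peaks of the list.

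Gene symbols were matched by name or unique synonym to a RefSeq table of GRCm38.p6, which names 2676 of the 2893 control genes and 1432 of the 1593 COH genes. It was used for names and for the neighbours of Rac1, and its coordinates are not given, since gene starts lay within 100 bp of those in the lists for 93 of 3175 genes and the median offset was 133 kb. Positions were not compared with mm9 here, so the build stays unsettled. For each of 25 gene lists, fixed before the data were examined, the members with a peak were counted and set against 10000 random lists of the same size drawn from 21900 protein-coding genes; the percentile describes these libraries and is no test of the conditions. Random lists matched on gene length had been planned as the main comparison and were not run, so the random lists are unmatched throughout. Whether gene length raised the count of any list was not measured. Of the 7 multicopy genes 4 are protein-coding, so the range drawn for that list is not one of like genes. The results of 1 of the 25 lists, and 1 member of another, are not reported here. For genes with a control peak, the number that also had a COH peak was set against random control genes from the same of 5 bins by best fold. A further 12 lists were written after the fixed lists had been seen and before their own members were looked up.

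Genes were named by a rule fixed before the data were examined: Rac1 and Kif2a; the genes of the 10 peaks of highest fold per library; those of the 10 overlapping pairs of smallest rank sum; the 5 genes with the most peaks per library; and up to 4 members per gene list, promoter peaks and high ranks first. Members listed beyond these, to complete a count, were named after their values had been seen, as were chromosomes X and 13 for their ratios. Alternatives fixed before the data were examined were peaks above the median fold, equal numbers of the strongest peaks, removal of clustered peaks, a reciprocal overlap of 50%, peaks within 1000 bp of each other, chromosomes 1 to 19 and X, and distance limits to the TSS. A -log10 q of at least 5, and removal of mitochondrial peaks and of peaks with a pileup above 100, were added after the data had been seen.

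The overlap and gene list steps were tested on simulated data. With 1000 planted pairs among simulated lists of 3078 and 1711 peaks, 1000 were recovered. Among 21900 genes, 1 of 100 simulated lists of 30 genes without enrichment and 19 of 20 lists with a 4-fold raised rate lay above the random range. All simulated genes without enrichment had the same rate. The simulation therefore does not show how often real lists, whose genes differ in length and expression, lie above the range through such traits. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.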

Results

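Binding profiles of an antibody against Rac1, a small GTPase that steers actin remodelling, were compared between the retina of untreated mice and the retina of mice with chronic ocular hypertension (COH), a model of glaucoma in which raised pressure in the eye injures the axons of retinal ganglion cells. The assay was CUT&Tag, in which an antibody bound to chromatin in nuclei tethers the Tn5 transposase, so that sequencing adapters are inserted around the bound sites. There were 2 libraries, 1 from control retina and 1 from retina after 1 week of COH, both from wild-type C57BL/6 mice 7 weeks old. The stated purpose was to search for genes and transcription factors related to Rac1. Each library is represented by the authors' list of peaks, 3078 for control and 1711 for COH. With 1 library per group there is no replicate spread, so no difference below was tested between the conditions, and intervals are exact 95% binomial intervals that cover counting error only. The lists do not give the number of reads, and no library made with a control antibody was analysed here.

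In both lists promoters held more peaks than any other annotation class, and the COH list was shorter by a larger factor there than far from genes. Peaks annotated to promoters numbered 1445 in control and 694 in COH, a ratio of 0.480. Peaks in 5' UTRs numbered 537 and 198, a ratio of 0.369, and 72.4% of them in control and 75.8% in COH lay within 1000 bp of a transcription start site (TSS). Distal intergenic peaks numbered 569 and 457, a ratio of 0.803, and intronic peaks 367 and 280, a ratio of 0.763. Exons held 127 and 61 peaks, 3' UTRs 22 and 14, and the regions just downstream of genes 11 and 7. The promoter share was therefore 46.9% (45.2 to 48.7) of the control list and 40.6% (38.2 to 42.9) of the COH list, a difference of -6.38 percentage points, while the distal intergenic share was 18.5% (17.1 to 19.9) and 26.7% (24.6 to 28.9). Peaks within 1000 bp of a TSS made up 61.6% (59.9 to 63.4) of control and 51.1% (48.7 to 53.5) of COH peaks, a difference of -10.5 points. These counts take no account of peak strength, with which the overlap between the lists rose. Of the control peaks in the highest of 5 bins by fold, 261 lay within 1000 bp of a TSS and 355 farther away. A loss particular to gene starts is therefore not shown.

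**Figure D1:**
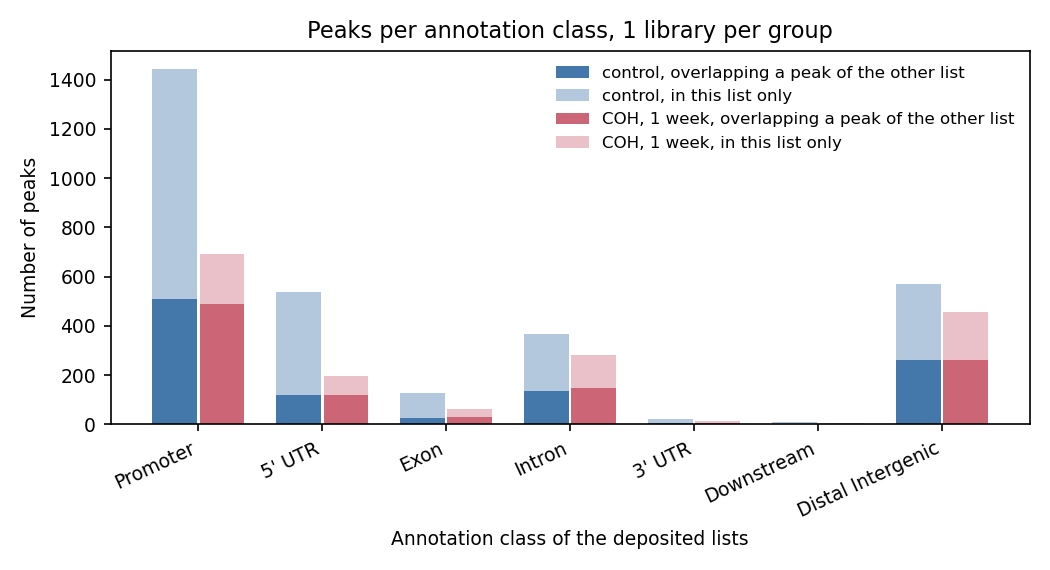
Number of peaks (vertical axis) in each annotation class of the deposited lists (horizontal axis) for the control and the COH library, 1 library each. The dark part of each bar counts peaks that overlap a peak of the other list by at least 1 bp and the pale part those that do not: promoters hold 1445 control and 694 COH peaks, distal intergenic regions 569 and 457.

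The control list held 1.80 times as many peaks as the COH list and covered 1523 kb against 792 kb. The peaks themselves were of like size, with a median length of 426 bp in control and 401 bp in COH. The authors' pileup had a median of 17 in control and 16 in COH. Chromosome X carried 83 control and 72 COH peaks, a ratio of 0.867, against 0.556 over all chromosomes, and chromosome 13 had the lowest ratio, 0.424, with 139 and 59 peaks. Chromosome Y had 7 and 6 peaks and the mitochondrial genome 4 in each list.

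Most COH peaks overlapped a peak of the longer control list. Of the 1711 COH peaks, 1058 (61.8%, 59.5 to 64.1) overlapped a control peak by at least 1 bp, and of the 3078 control peaks, 1056 (34.3%, 32.6 to 36) overlapped a COH peak. When the COH peaks were placed at random on the same chromosomes, a median of 5 and at most 10 overlapped in 1000 placements. The placements ignored the position of gene starts, whereas 61.6% of control and 51.1% of COH peaks lay within 1000 bp of a TSS. They therefore cannot separate binding of the same sites from a concentration of both lists near gene starts. The overlap rose with the strength of the peak in both lists. Control peaks with a COH partner had a median fold enrichment of 6.05 and those without 4.95, by the fold that the authors' peak caller gave. Among control peaks within 1000 bp of a TSS, the overlapping share was 17.9% (14.2 to 22.1) in the lowest of 5 bins by fold and 55.9% (49.7 to 62.1) in the highest. Farther from a TSS it was 21.4% (16.3 to 27.2) in the lowest bin and 79.4% (74.9 to 83.5) in the highest. In the bins between, the share was higher near a TSS, with overlapping intervals: 23.1%, 29.8% and 36.8%, against 14.4%, 21.1% and 33.7% farther away. Among COH peaks within 1000 bp of a TSS, 47.4% (39.7 to 55.1) overlapped a control peak in the lowest bin and 92.1% (84.5 to 96.8) in the highest. Requiring a reciprocal overlap of 50% lowered the share of COH peaks to 52.0%. With the control list cut to its 1711 strongest peaks, as many as the whole COH list holds, most COH peaks had no partner among them.

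**Figure D2:**
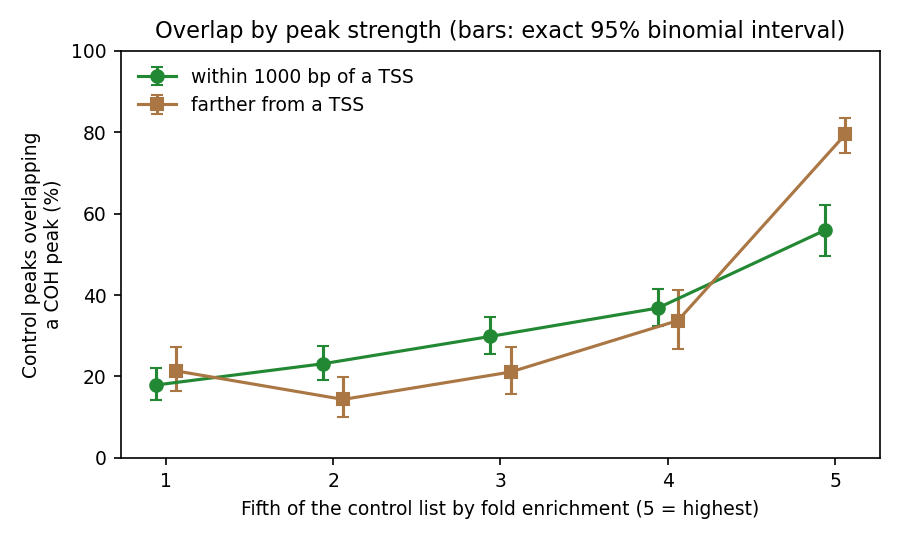
Percentage of control peaks that overlap a COH peak (vertical axis) in 5 bins of the control list by fold enrichment (horizontal axis), for peaks within 1000 bp of a TSS and for peaks farther away; error bars are exact 95% binomial intervals and each library is a single one. The share lies at 17.9% in the lowest and 55.9% in the highest bin near a TSS, and at 21.4% and 79.4% away from it. In the bins between, the share is higher near a TSS.

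The 10 strongest sites by fold were the same in both retinas and lay away from promoters. The 10 genes assigned to the peaks of highest fold were the same 10 in control and in COH, and their peaks also formed the 10 overlapping pairs with the smallest rank sum. The strongest lay at -23380 bp from the TSS of the predicted gene Gm5614 (negative values lie upstream), at 35216511 to 35216890 on chromosome 9 in the coordinates of the lists, with a pileup of 3958 in control and 4744 in COH. The next were an intronic site of Ppp1r9a, which encodes the actin-binding protein neurabin-1, and distal sites near Gm27236, Gm14496, A630089N07Rik and Gm5626. An intronic site of Filip1l, distal sites near Gm20039 and the sensory-neuron receptor gene Mrgprd, and a site in an intron of Cdk8 assigned to Gm15739 completed the 10. Of the 20 control peaks of highest fold, 17 overlapped one of the 20 COH peaks of highest fold, and of the 50 highest, 41 overlapped one of the COH 50. Of the 20 control peaks of highest pileup outside the mitochondrial genome, 20 overlapped a COH peak and 4 lay within 1000 bp of a TSS. The genes with the most peaks were Rpl31-ps7 (10 in control, 8 in COH), Snurf (9 and 7), Asmt (8 and 7) and Ezh2 (8 and 5), whose peaks include ones in clusters of at least 5 peaks within 100 kb. Apba2 with 5 control peaks and Gm11400 with 6 clustered COH peaks completed these ranks.

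The peaks were assigned by the authors to 2893 genes in control and 1593 in COH. Both lists named 1029 of them, 1864 were named in control only and 564 in COH only. Among 21900 protein-coding genes, 2363 (10.8%) had a control peak and 1179 (5.38%) a COH peak. Both were found for 772, where 127 would be the number for independent lists. That number takes every protein-coding gene as equally likely to carry a peak. It cannot separate binding of the same genes from a preference of both lists for the same kind of gene. A gene named in both lists need not have overlapping peaks. Counting only peaks within 1000 bp of a TSS, 589 genes were in both lists, 1298 in control only and 283 in COH only.

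Kif2a, which encodes a kinesin that depolymerises microtubules and is named in the title of the series, carried 1 peak in control and 0 in COH. The control peak lay at 107158839 to 107159231 on chromosome 13, in the promoter, at -205 bp from the TSS, with a pileup of 14, a fold of 4.31 and a -log10 q of 3.69. It ranked 2558 of 3078 by fold. Of the 386 control peaks in the same lowest bin by fold and within 1000 bp of a TSS, 69 (17.9%, 14.2 to 22.1) overlapped a COH peak, so most peaks of that strength had no partner. No COH peak lay within 100 kb of the Kif2a TSS, and the nearest, assigned to Zswim6, lay 867394 bp away. The Kif2a peak was not among the control peaks above the median fold or among those with a -log10 q of at least 5. Rac1 itself had no peak in either list, and of 10 neighbouring protein-coding genes Usp42 alone had a peak, in control. The genome build of these coordinates is not settled: the submitters' processing notes name mm9, and gene starts in the lists lay within 100 bp of those of GRCm38.p6 for 93 of 3175 genes.

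Kinesins as a family did not stand apart, with 5 of 46 (10.9%, 3.62 to 23.6) in control and 2 (4.35%, 0.531 to 14.8) in COH, both inside the random range. Besides Kif2a, promoter peaks in control marked Kif1b, a motor for mitochondria and synaptic vesicle precursors (fold 5.12), and Kif27 (5.08), and in COH Klc4, a kinesin light chain (4.02). Kif13b was the member in both lists, through overlapping peaks in an exon of another gene at -59343 bp from its TSS in COH. Microtubule and neurofilament genes had 9 of 51 members with a control peak and 5 with a COH peak, both inside the range. Camsap1, which binds microtubule minus ends, had promoter peaks in both, Stmn1 had overlapping peaks at its start, and Map2 (fold 5.97) and Map4 (4.23), microtubule-associated proteins, had promoter peaks in control only. Axon guidance genes had 5 of 56 in each list and none in both, where random control genes of like fold had a median of 1 (0 to 3). With a -log10 q of at least 5, 0 had a control peak, below the random range of 1 to 8. Ephb3, an ephrin receptor, and Ablim1, an actin-binding protein, had COH promoter peaks, Neo1, a receptor for guidance cues, had a control promoter peak, and the Unc5c peak in COH was distal.

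Axon injury and regeneration genes carried peaks often in both retinas. Of 43 members, 13 (30.2%, 17.2 to 46.1) had a control peak and 10 (23.3%, 11.8 to 38.6) a COH peak, above random ranges of 1 to 9 and 0 to 6, and 8 had both. Mapk8 and Mapk9, the JNK kinases that signal axon damage, had promoter peaks in both lists (fold 6.78 and 6.24 in control, 6.59 and 4.97 in COH). Atf4, Bdnf, Igf1r, Ppp3ca and Stat3 were also among the members in both lists. The overlapping Bdnf peaks were distal, at -38873 bp from the TSS in control and -38835 bp in COH. Counting only peaks within 1000 bp of a TSS, 10 members had a control peak and 7 a COH peak. These counts lay above random ranges of 1 to 8 and 0 to 5, and Bdnf, Igf1r and Ntrk2 were not among them. Rtn4, which encodes the growth inhibitor Nogo (fold 7.04), and Tsc1, a brake on mTOR (6.19), had promoter peaks in control only, and Klf7 and Ntrk2 had peaks in COH only. Among peaks above the median fold, and among equal numbers from each list, the control count was 8, still above its random range. The random lists came from all protein-coding genes, so they do not set this list apart from broadly expressed genes. In control, chromatin regulators (48.5%), chaperones (35.0%) and splicing factors (30.8%) had like or higher shares. Ribosomal protein, oxidative phosphorylation, mitochondrial ribosome, proteasome and tRNA synthetase genes had lower ones, 2.70% to 12.5%. All but tRNA synthetases had intervals that overlapped that of this list.

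Other injury lists lay inside the random range in both libraries. Apoptosis genes had 7 of 37 members with a control peak and 4 with a COH peak; cytochrome c (Cycs), the survival gene Bcl2l1 and Apaf1, which forms the apoptosome, had overlapping peaks, and Ripk1 had a control promoter peak. The apoptosis count of 7 lay above the control random range once peaks below the median fold were left out, with equal numbers and with a -log10 q of at least 5, where the ranges ended at 5, 5 and 6. Oxidative stress genes had 4 of 35 and 3, none in both, with control promoter peaks at Txn1, Nfe2l2 and Sod1 and a COH 5' UTR peak at Sod2. Glial reactivity and inflammation genes had 1 of 36, Stat3, in control and 3 in COH, Stat3, Nfkbia and Irf8. Glaucoma-associated genes had 5 of 38 and 3, none in both, with promoter peaks at Mfn2, Tbk1 and Gmds in control and at Col11a1 in COH. Synapse and ion channel genes had 8 of 46 and 5, with promoter peaks of the vesicle calcium sensor Syt1 in both lists, of Pclo in control and of Nrxn2 in COH, and a distal peak near Glra2 in both.

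Of the 24 lists, circadian and immediate early genes had the highest share of members with a peak in both libraries. In control 13 of 27 (48.1%, 28.7 to 68.1) had a peak, and in COH 13 of 27, against random ranges of 0 to 6 and 0 to 4. The same gene carried a peak in both retinas for 9 members: the clock repressors Per1, Per2 and Per3, the nuclear receptor Nr1d2, the clock output factors Dbp and Tef, the immediate early genes Egr1 and Nr4a3, and Jund, a subunit of the AP-1 transcription factor. Nr1d2 had a promoter peak with a pileup of 59 and a fold of 7.89 in control, and of 60 and 7.87 in COH. The peaks of Nr4a3 in the 2 lists did not overlap each other. Promoter peaks of Per1 and Per3 overlapped between the lists, and Cry1 (fold 6.40) had one in control only. Btg2, Cry2 and Fos were the other members in control only, and Arntl, Fosb, Nr1d1 and Nr4a1 those in COH only. Of the 13 control genes, 9 also had a COH peak, against a median of 4 in random control genes of like fold (percentile 99.8). The control count was 6 among peaks above the median fold and with equal numbers, above random ranges that ended at 4. Of the 10 reported lists with at least 5 control genes, this list, axon injury genes (8 of 13, random median 4) and transcription factors (8 of 12, random median 3) had more genes also in COH than the central 95% of random control genes, and 7 lay inside.

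Retinal and stress transcription factors had 12 of 61 members (19.7%, 10.6 to 31.8) with a control peak, inside the random range of 2 to 12, and 10 (16.4%, 8.15 to 28.1) with a COH peak, above 0 to 7; 8 had both. The architectural factors Yy1 and Ctcf, the neuronal factor Mef2a and the cytokine-activated Stat3 had overlapping promoter peaks. Creb1, Egr1, Sp1 and Thrb were the other members in both lists. With a -log10 q of at least 5, the control count of 9 was above its range, which ended at 8. Several lists share members: Stat3 belongs to 3 of them. Of the members with a peak, the transcription factor list also shares Egr1 and Fos with the circadian list and Klf7 with the axon injury list. The counts of these lists are therefore not independent.

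No list of retinal cell-type markers lay above its random range. These ranges start at 0 in both libraries, so no such list could have fallen below. Among all protein-coding genes, 10.8% had a control peak and 5.38% a COH peak. Rod photoreceptor markers had 0 of 21 in both libraries and horizontal cell markers 0 of 9. Ganglion cell markers had 2 of 22 in control, an exonic Nefm peak and a peak assigned to Isl2 that lies 93361 bp from its TSS, and 0 in COH. Cone markers had 1 of 13 in each list, Thrb, bipolar cell markers 0 of 17 and 1, Grik1, and amacrine cell markers 2 of 17 and 1, with Slc6a9 in both and Tfap2a in control. Müller glia markers had 3 of 16, with promoter peaks at Car2 and Glul, and 2, distal or intronic peaks assigned to Aqp4 and Sox9. Astrocyte (1 of 8, Slc1a2), microglia and macrophage (2 of 17, Mrc1 and P2ry12), vascular (1 of 16, Cldn5) and pigment epithelium markers (1 of 12, Tyr) had control peaks and 0 in COH. The peaks assigned to Tyr, P2ry12 and Aqp4 lay in introns of other genes (Nox4, Med12l and Chst9), that of Tyr 116216 bp from its TSS. Ribosomal protein genes had 5 of 51 in control and 2 in COH, with Rps23 in both. Of 7 genes known for multicopy reads, Sfi1 and Pisd-ps1 had clustered peaks in both lists.

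**Figure D3:**
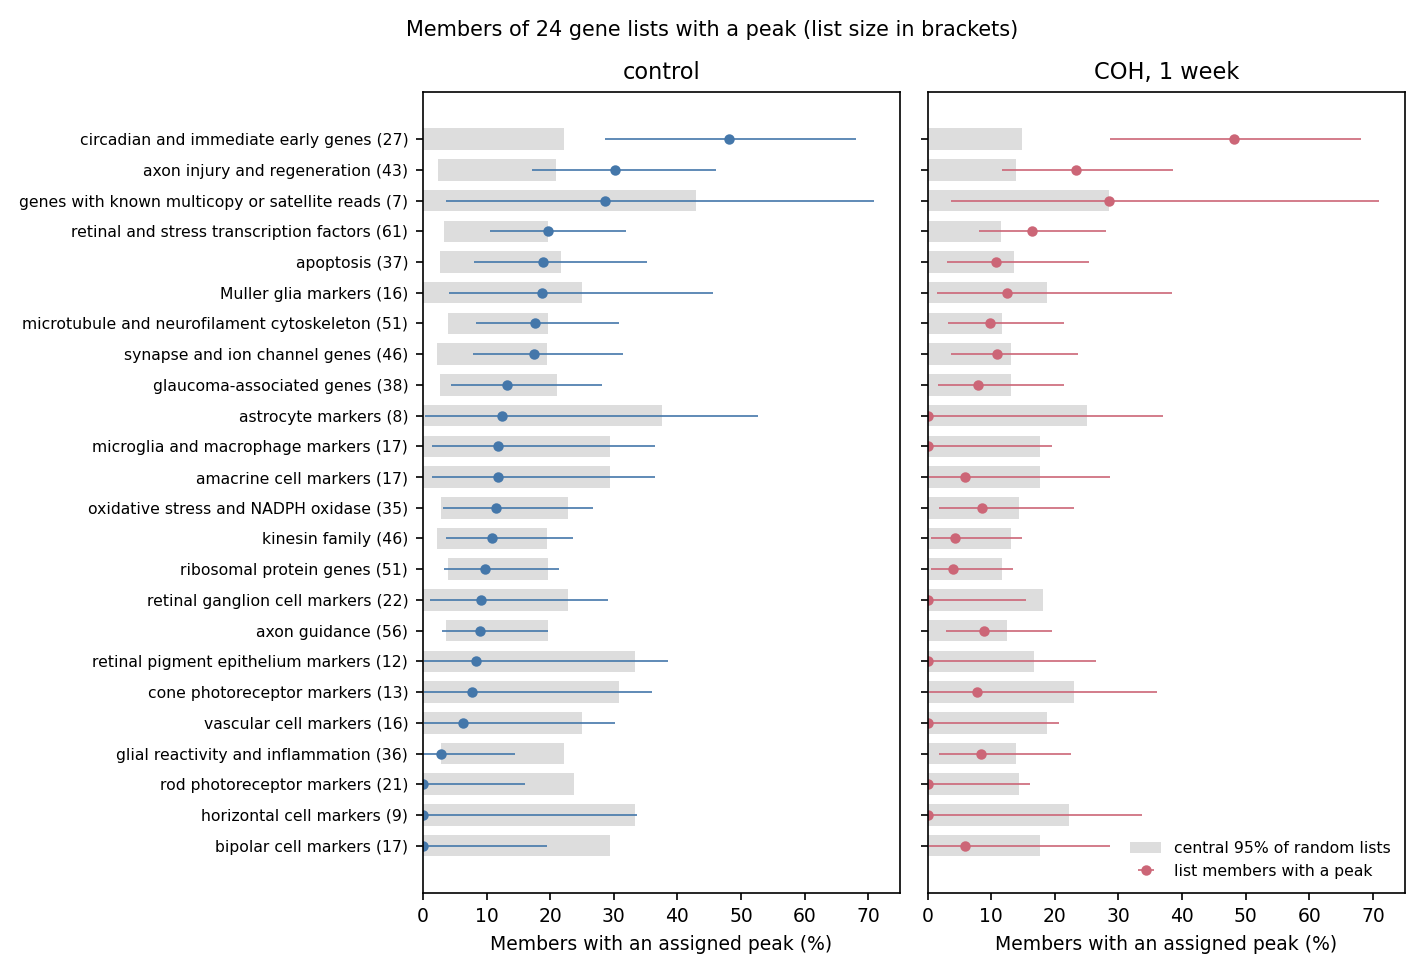
Percentage of the members of each of 24 gene lists that have an assigned peak (horizontal axis; list size in brackets) in the control library and in the COH library, with exact 95% binomial intervals as lines and the central 95% of 10000 random lists as grey bars. Circadian and immediate early genes lie at 48.1% in both, and axon injury and regeneration genes at 30.2% and 23.3%, beyond the grey bars.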

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

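The settings with a -log10 q of at least 5, and without mitochondrial and high-pileup peaks, were chosen after the data had been seen. The control list stayed longer, with a ratio to COH of 1.82 to 1.87 without clustered peaks, with a -log10 q of at least 5 and without mitochondrial and high-pileup peaks, against 1.80 for all peaks, and the promoter share stayed lower in COH than in control in all 6. Shares count as moved where they left their exact interval or where a gene list changed sides of the random range, and counts where they differ by over 1.5 times; stricter selections lower counts by construction. Circadian and immediate early genes and axon injury genes lay above the random range in both libraries in all 6 settings. Read depth is unknown, so its effect on weak peaks such as that of Kif2a was not measured. No paired analysis was possible because each group has 1 library and no result comes from a test. Random lists matched on gene length were not run.

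Above the median fold, 1541 control and 856 COH peaks were left, of which 36.6% and 65.9% overlapped; 552 genes were in both lists, 945 in control only and 276 in COH only, and Kif2a had 0 control peaks. The percentage of members with a control peak was 0 for amacrine, astrocyte and vascular markers, kinesins, axon guidance and oxidative stress genes, 7.84 for microtubule genes, 18.9 for apoptosis, 6.52 for synapse genes, 9.84 for transcription factors and 22.2 for circadian and immediate early genes. With a COH peak it was 0 for cone and amacrine markers, kinesins and oxidative stress genes, 1.96 for microtubule genes, 2.70 for apoptosis and 18.5 for circadian and immediate early genes.

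With a -log10 q of at least 5, 1945 control and 1041 COH peaks were left, of which 38.8% and 72.5% overlapped; 51.1% of control peaks were promoter peaks, 1137 genes were in control only and 258 in COH only, and Kif2a had 0 control peaks. Members with a control peak made up 0% of ganglion cell, amacrine and vascular markers and axon guidance genes, the last now below the random range, 2.17% of kinesins, 18.9% of apoptosis genes and 14.8% of transcription factors. Members with a COH peak made up 0% of cone markers, kinesins, oxidative stress and glaucoma-associated genes and 28.6% of multicopy genes, a list whose random range is void since 4 of its 7 members are protein-coding.

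Equal numbers meant the 1711 strongest control peaks by fold against the whole COH list. With equal numbers, 46.2% of control and 46.3% of COH peaks overlapped, 48.7% of control peaks were promoter peaks and 868 genes were in control only. Control percentages were 0 for amacrine, astrocyte and vascular markers and axon guidance genes, 7.84 for microtubule genes, 18.9 for apoptosis, 2.86 for oxidative stress, 6.52 for synapse genes, 9.84 for transcription factors and 22.2 for circadian and immediate early genes. With a reciprocal overlap of 50%, 28.9% of control and 52.0% of COH peaks overlapped. With promoters taken as within 1000 bp of the TSS, shares were 61.6% and 51.1%, a difference of -10.5 points. Counting only peaks within 1000 bp of the TSS, 589 genes were in both lists and 283 in COH only; control percentages were 0 for amacrine, microglia and pigment epithelium markers and 6.52 for synapse genes, and COH percentages 0 for bipolar, amacrine and Müller glia markers. Without clustered peaks, multicopy genes had 0% in both lists. The cause of these moves was not tested beyond the smaller number of peaks.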

Other observations

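The 12 further gene lists were chosen after the fixed lists had been seen. The tests of depth, enrichment, open promoters and repeated sequence were also chosen after the results they bear on had been seen, and those of the cyclic AMP response element (CRE) and clock output lists before.

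Chromatin regulators carried Rac1 antibody peaks often in both libraries. Of 66 members, 32 (48.5%, 36 to 61.1) had a control peak and 22 (33.3%, 22.2 to 46.0) a COH peak, above random ranges of 2 to 12 and 0 to 7, and 20 had both. Promoter peaks of the histone demethylase Kdm3a and of the acetyltransferase Ep300 overlapped between the lists, and the deacetylase Hdac2 had one in control only (fold 8.03). Of the 32 control genes, 20 also had a COH peak, against a median of 11 for random control genes of like fold (percentile 99.97). Ezh2 counts in both lists, and its COH peaks are distal and clustered.

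Chaperone and unfolded protein response genes had 14 of 40 members with a control peak and 9 with a COH peak, above ranges of 1 to 8 and 0 to 5, with overlapping promoter peaks at Hspa8 and Dnajb9 and control promoter peaks at Hsph1 and Dnaja2. Splicing factors had 16 of 52 in control, above 2 to 10, and 5 in COH, inside 0 to 6. All 5 of these, with Rbm39 and Snrnp70 among them, also had a control peak, which for 16 control genes is near the median of 4 for random control genes of like fold (1 to 8). Chaperone genes had 5 of 14 in both, at the random median of 5. Of the 8 further lists with at least 5 control genes, chromatin regulators alone lay above the range in this comparison. Mitochondrial ribosome genes had 6 of 48 in control and 0 in COH, inside ranges of 1 to 10 and 0 to 6, and the control peak at Mrps18b overlaps a COH peak that was assigned to another gene. Also inside the range in both libraries were CRE target genes (6 of 35 and 3), oxidative phosphorylation (5 of 50 and 4), proteasome (2 of 31 and 3), DNA repair (3 of 55 and 1), cilium and outer segment transport (6 of 50 and 3), autophagy and lysosome (5 of 44 and 2) and tRNA synthetases (1 of 37 and 3).

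The COH list held fewer peaks than control, 1711 against 3078. The lowest implied background pileup had a ratio of COH to control of 0.967, if the assumed form of the fold holds. This ratio cannot decide on lower sequencing depth. The scaling of the pileups, any background library and the treatment of duplicate reads are not known. Weaker enrichment in the COH library could have lost the weak peaks first, but the test of it was void. The overlapping share of control peaks near a TSS was 17.9% in the lowest bin by fold and 55.9% in the highest, and that of COH peaks against control was 47.4% and 92.1%, so strong peaks were shared more from either side. Lower depth, weaker enrichment and a true loss of signal in COH retina therefore all stay open, with 1 library per group.

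Circadian and immediate early genes carried peaks in 48.1% of members in both libraries. If open promoters in general were the cause, ribosomal protein genes and rod markers should reach a like rate; 5 of 72 had a control peak, with an upper bound of 15.5%, below the lower bound of 28.7% for the clock and immediate early genes. Those genes were pooled after their counts had been seen, and lists taken as broadly expressed lay on both sides. Of 8 such lists, ribosomal protein genes among them, 5 had an upper bound below 28.7% in control. Chromatin regulators (48.5%), chaperones (35.0%) and splicing factors (30.8%) had intervals that reach it. The explanation therefore stays undecided, and promoter openness was not measured here. A candidate explanation is a shared factor at CRE sites or at clock-controlled promoters. Other CRE target genes had 6 of 35 members with a control peak, at percentile 87.5 of random lists, and other clock output genes 4 of 19, at percentile 90.2, neither above the range nor at the median. Their intervals, 6.56% to 33.6% and 6.05% to 45.6%, overlap that of the clock and immediate early genes, 28.7% to 68.1%, and the explanation was left open. In COH, 5 of 19 clock output genes had a peak, above the range of 0 to 3. The time of day of collection was not tested.

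The 10 peaks of highest fold were the same sites in both lists, as were 17 of the 20 highest. Reads piled up on repeated sequence may account for this, as 20 of the 20 control peaks of highest pileup overlapped a COH peak and 4 of the 20 lay within 1000 bp of a TSS. Real binding present in both retinas would overlap as well, and the 2 cannot be told apart without the sequence of the sites.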
